A study of Nicotiana tabacum with 2 samples.

How the data were processed

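Small RNA of tobacco (Nicotiana tabacum, cultivar K326) roots was sequenced from field-grown plants before and after topping, the removal of the flowering shoot top, with 1 library per condition. Per the labels' protocols, RNA of 18 to 26 nt was excised from a gel loaded with about 100 μg of total RNA, ligated to adapters, amplified and sequenced on the Solexa platform. Trimming and quality filters are not given in the sources used here.

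The authors deposited, per library, a list of distinct sequences (tags) of 18 to 30 nt with their read counts, a list of tags under 18 nt with counts, and a table of counts per length. These counts are not normalized. The table of counts per length held 816 reads before and 3606 reads after topping more than the tag lists, and totals were taken from the tag lists. The 18 to 30 nt lists held 12104207 reads in 3633398 tags before topping and 11292018 reads in 3084102 tags after topping. The authors' tables of conserved and new miRNAs give a signal for the before library, per the deposited readme, which was 2.16 times the tag count of the same sequence (median over 161 sequences). The basis of this factor is not stated. The fold change in the authors' deposited table is a signed score, with a minus sign for lower abundance after topping per the readme. The readme gives both read columns of these tables the same condition, so 2 per-library columns could not be assigned and were not used. Every count for the tables' sequences was taken from the tag lists. The conserved table has 111 entries with 72 distinct sequences, and the new table has 126 entries with 90 distinct sequences, 1 of which matched no tag and was not analysed here.

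Reads were counted for 42 families, described by 71 mature sequences written from general knowledge before the data were examined. A tag was given to a family with at most 2 mismatches, a start within 1 nt and an end within 2 nt, and tags equally close to more than 1 family were dropped. The ratio of shares of clean reads, after over before, was given its exact (Clopper-Pearson, conditional binomial) 95% interval. A family or table entry was called higher or lower when the ratio was at least 2 or at most its inverse, the interval excluded 1, and both libraries together held at least 20 reads. A library with no read gave only a bound from a floor of 3 reads. Shares have Wilson 95% intervals. Intervals and floors cover counting error only, and they may be too narrow even for that, since PCR copies are not independent molecules. No p-value was computed, because 1 library per condition leaves no replicate error, and all statements compare these libraries, not the conditions. Data of 5000 tags were simulated with the depth of these libraries and with Poisson counting error only. Of these, 89 of 100 tags with a 3-fold change and 100 of 100 with a 6-fold change were called. Of 4800 unchanged tags, 78 were called wrongly. Variation between plants, library preparations or PCR was not simulated, so this is not the rate of wrong calls in the real libraries.

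Families were grouped by known targets into auxin, development, nutrient, copper, defence, silencing machinery and Solanaceae lists. The median log2 ratio of each list was placed among 10000 random lists matched on abundance where the list had at least 3 measured members. Random lists were drawn from the same measured families, those of the list included, so the percentiles have no independent background. Distinct tags were also compared after thinning both libraries to 11000000 reads by the exact expectation. Named in the text were the 5 families with most reads per library, up to 10 called families with the highest and 10 with the lowest ratios, all families of lists with at most 5 measured members, and in each authors' table the 3 most abundant entries per library with the 5 highest and 5 lowest called ratios, besides the 5 most abundant tags per library.

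Sequences for ribosomal RNA, 13 transfer RNA ends, a small nuclear RNA, chloroplast RNA, star strands and virus proteins were listed from general knowledge after the most abundant tags had been seen, and no genome sequence was used here. Tags of 20 to 24 nt were translated in all frames on both strands and matched exactly to listed virus proteins. For tobacco mosaic virus (TMV) these were the coat and movement proteins and a part of the polymerase. For potato virus Y (PVY) it was the coat protein, and the cucumber mosaic virus (CMV) coat protein served as background. Tags with at least 4 reads and over 20 times as many as in the other library were also assembled through shared 17-nt words into contigs of at least 60 nt, which were compared with the same proteins by tblastn at an e-value limit of 0.001. These contigs were selected for a difference between the libraries, so only the translated tags measure that difference.

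Alternatives were scaling by reads of 20 to 22 nt, by the sum of family reads, by edgeR TMM factors or by DESeq2 size factors, stricter matching, other read minimums of 0 or 100, and a ratio of 1.5. Scaling without reads on the library-specific contigs, and without these and alanine tRNA fragments, was added after seeing the data, as was the addition of unmatched miR171d forms to their family. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9, BLAST+ 2.17.0, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.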

Results

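Small RNA from tobacco roots was sequenced in 1 library before topping, with 12104207 clean reads of 18 to 30 nt, and in 1 library after topping, with 11292018. The design asks which miRNAs differ in roots after the shoot top is removed. There were no replicates, so no difference below has a replicate check, and each is a difference between these 2 libraries. Of 6131192 distinct tags, 586308 occurred in both libraries, and these held 62.3% of the reads before topping and 59.5% after topping.

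The libraries also differed in virus-derived reads, which stand beside every comparison that follows. Reads translating to the TMV coat protein numbered 213624 in the after library and 138 in the before library, where 54 sense and 70 antisense reads also matched the listed TMV coat gene exactly. Reads translating to the PVY coat protein numbered 40445 in the before library and 37 in the after library. The CMV coat protein, used as background, matched 94 reads before and 179 reads after topping. Tags specific to the before library assembled to 76 contigs with 9.24% of its reads, of which 6 contigs with 0.386% of its reads matched a listed virus protein. Those specific to the after library gave a different set of 36 contigs with 17.6% of its reads, of which 13 with 3.95% matched. The list held the PVY coat protein and, for TMV, the coat and movement proteins and 164 amino acids of the polymerase. Contigs from other parts of these viruses could not match, and the origin of the other contigs was not tested.

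Reads of 18 to 20 nt made up 23.7% (23.6 to 23.7) of the before library and 30.4% (30.4 to 30.5) of the after library. Reads of 24 nt, the length of most heterochromatic siRNAs, took 15.6% before and 12.8% after topping, while reads of 21 nt, the length of most miRNAs, took 21.6% and 22.3%. Reads of 27 to 30 nt took 7.46% and 2.89%. Adenine began 54.0% of the 24-nt reads before topping and 48.2% after, and uracil began 38.3% and 32.4% of the 21-nt reads. Over distinct tags these differences shrank from -5.79 to -2.78 percentage points for adenine and from -5.85 to -1.04 for uracil. Guanine began 20.5% of the 24-nt reads before topping and 25.1% after. Fragments of alanine tRNA, which begin with guanine, held 41935 of the 24-nt reads before and 89588 after, so they lower the adenine share of the after library. Thinned to 11000000 reads, the libraries held 3369139 distinct tags before and 3019714 after topping. Without reads on the library-specific contigs, a setting chosen after seeing the data, the difference at 18 to 20 nt was 6.67 percentage points against 6.77 with them.

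**Figure D1:**
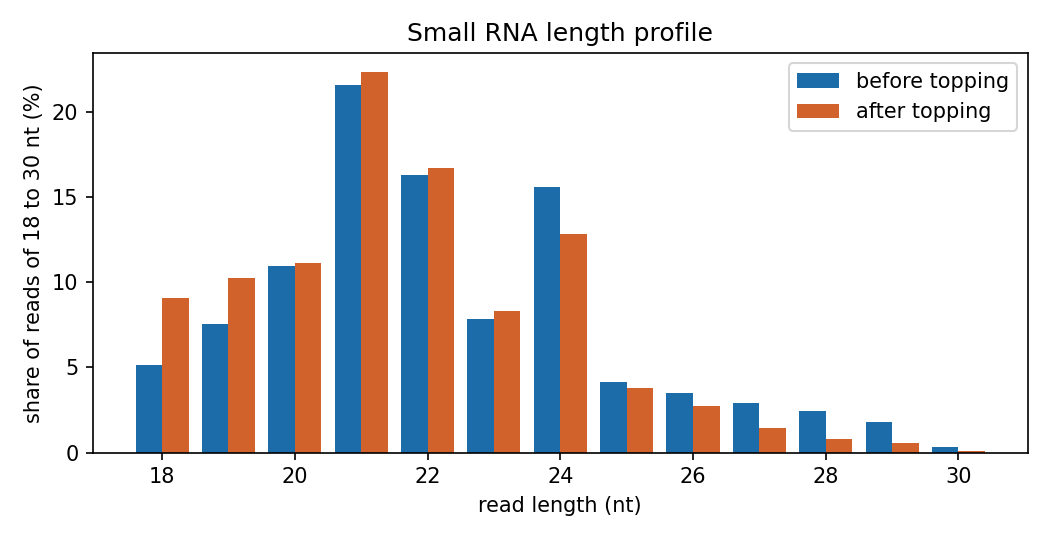
Share of reads of 18 to 30 nt (%) at each read length (nt), as bars from 0, for the before and the after library. The after library has a larger share at 18 nt (9.06% against 5.13%) and a smaller one at 24 nt (12.8% against 15.6%).

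The most abundant tag before topping was TTGATACGCACCTGAATCGGC, with 201752 reads before and 157098 after. It was followed by TGACAGAAGAGAGTGAGCAC, the main miR156 form, with 111652 reads. The other 3 of the 5 most abundant tags before topping, GGGGATGTAGCTCAGATGGTA, GGGGATGTAGCTCAGATGGT and GGGGATGTAGCTCAGATGGTAGA, were 5′ ends of alanine tRNA. In the after library the most abundant tag was GGGGATGTAGCTCAGATGGTAGA with 165380 reads, and GGGGATGTAGCTCAGATGGTAG, GGGGATGTAGCTCAGATGGTA and GGGGATGTAGCTCAGATGGTAGAG were also among the first 5. Fragments of this tRNA took 2.87% of reads before and 5.02% after topping, a ratio of 1.75 (1.74 to 1.76). The listed ribosomal RNA took 1.33% (1.33 to 1.34) and 1.40% (1.40 to 1.41), and the listed chloroplast RNA took 0.00826% and 0.00871%. The 10 most abundant tags held 6.19% of reads before and 7.04% after topping, and the 100 most abundant held 12.5% and 13.5%. Of all deposited reads, 12.1% before and 15.5% after topping lay outside the excised range of 18 to 26 nt.

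Conserved miRNA families together took 2.27% of reads in the before library and 1.07% in the after library, a ratio of 0.471 (0.468 to 0.474). Of 30 families with enough reads, 7 were lower and 2 were higher in the after library. miR156/miR157, which targets the SPL factors of phase change, had 193990 reads before and 71952 after, a log2 ratio of -1.33. The same direction was seen for miR159, a regulator of GAMYB factors (-1.39), and for miR394 (-1.41). Lower values were also found for miR6024 (-1.71), miR6025 (-1.21), miR482/miR2118 (-1.09) and miR4376 (-1.07). Higher in the after library were miR398, which targets copper/zinc superoxide dismutases, with 27 and 106 reads (ratio 4.21, 2.74 to 6.68), and miR2111, a phosphate-related family, with 7 and 21 reads (ratio 3.22, 1.32 to 8.95). The other families among the 5 most abundant of either library did not pass the ratio of 2, with log2 ratios of -0.62 for miR165/miR166, -0.88 for miR172 and -0.88 for miR164 in both, -0.80 for miR167 before topping and -0.20 for miR168 after topping.

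These calls, and the directions of many families not called, depend on the total used for scaling. Of the called families, only miR4376 changed sign under another scaling, to 0.020 with the family sum. Scaling by the sum of family reads raised every log2 ratio by 1.09, TMM by 0.66 and DESeq2 size factors by 0.58. After these, 0, 1 and 1 families were lower and 9, 7 and 6 were higher. The family sum rests mostly on miR156/miR157, itself called lower, which held 70.6% of family reads before and 59.6% after topping. DESeq2 size factors put the median of the families, -0.58 in the main setting, at 0 by construction. miR6024 remained lower under TMM (-1.05) and DESeq2 (-1.13), and miR398 and miR2111 were higher under each scaling. For miR2111 the log2 ratio was 2.42 without mismatches and 2.27 with exact matches only, the latter without a call. Stricter matching dropped the main tag of miR6024, with 63 and 14 reads, and left that family without a call. Counting only exact matches of the listed sequences turned miR398 to a log2 ratio of -1.71 on fewer than 20 reads. Excluding reads on the library-specific contigs from the total, a setting chosen after seeing the data, left 5 families lower and 3 higher, and miR482/miR2118 (-0.95) and miR4376 (-0.93) were no longer called.

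**Figure D2:**
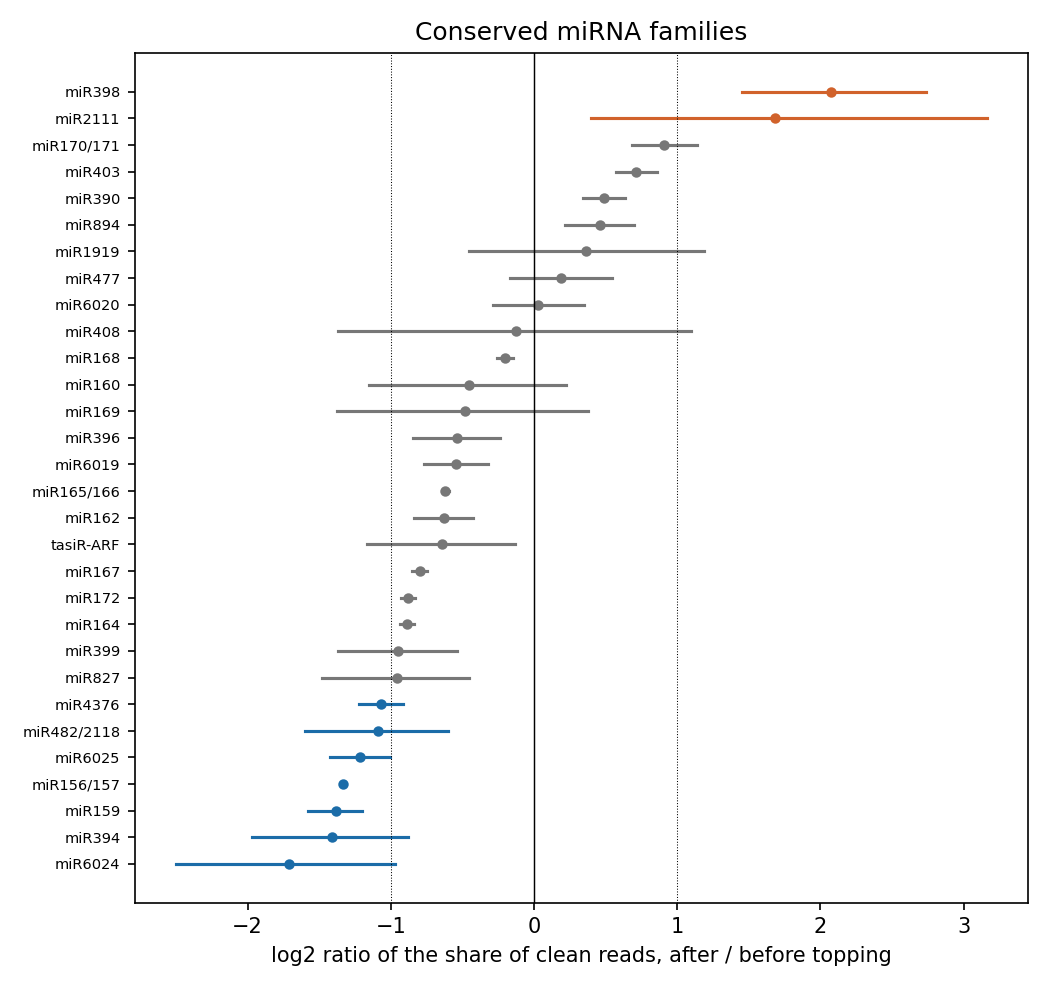
Log2 ratio of the share of clean reads, after over before topping, for the 30 families with enough reads, with 95% counting intervals as bars and the ratio of 2 as dotted lines. The 7 families called lower lie between -1.71 (miR6024) and -1.07 (miR4376), and all points move up by 0.58 to 1.09 under the scalings over families, where 14 of the 26 named families change sign under the family sum, miR4376 being the called family among them.

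By target group, the development list had 3 of 8 measured families lower and 0 higher, with a median log2 ratio of -0.88, at percentile 12.0 among random lists. The matching left out 2 miR171d forms with 340 reads before and 2248 after topping. With them, an alternative chosen after seeing the data, miR170/miR171 had a ratio of 4.89 (4.47 to 5.36) and 1 development family was higher. The 4 auxin families had 0 calls and a median of -0.55 (percentile 57.1), with miR390, the trigger of TAS3 siRNAs, at 0.49, miR160 at -0.45 and the TAS3-derived siRNA tasiR-ARF at -0.64. miR390 stood at 0.77 with exact matches only and at 1.06 without mismatches, the latter past the ratio of 2. Of 4 nutrient families only miR2111 was called, and miR399 and miR827, both of phosphate homeostasis, had values of -0.95 and -0.96, with miR169 at -0.48 (list median -0.72, percentile 15.5). On fewer than 20 reads, miR399 turned to 1.10 without mismatches and miR169 to 1.10 with exact matches only. Of 4 defence families, which target resistance genes of the NBS-LRR kind, miR482/miR2118 and miR6024 were lower, while miR6019 and miR6020 had values of -0.54 and 0.03 (median -0.82, percentile 17.9). The call of miR482/miR2118 was lost without reads on the library-specific contigs in the total, and that of miR6024 was lost under stricter matching. The 3 families that target the silencing machinery had 0 calls, with miR168, which targets ARGONAUTE1, at -0.20, miR162, which targets DICER-LIKE1, at -0.63 and miR403, which targets ARGONAUTE2, at 0.71 (median -0.20, percentile 80.7). The direction of miR403 turned to -1.35 with exact matches only, on 145 reads before and 53 after, which is past the ratio of 2. Its most abundant tag, a 19-nt form, had 292 and 719 reads. Of 3 Solanaceae families, miR4376 and miR6025 were lower and miR1919 stood at 0.36 (median -1.07, percentile 7.97), and the call of miR4376 was also lost without reads on those contigs in the total. The copper list had only 2 measured families, miR398 and miR408 (-0.12), and a median of 0.98. The value of miR398 turned to -1.71 with exact matches only, on fewer than 20 reads, and to -2.07 without mismatches. Also listed was miR397, with 9 reads before and 3 after, too few for a call. The authors' entry miR397b, with 137 and 39 reads (-1.71), was not counted in that family. Scaled by the sum of family reads, all 7 medians were above 0. Beside each of these lists, reads translating to the TMV coat protein numbered 138 before and 213624 after topping, and those translating to the PVY coat protein numbered 40445 and 37.

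In the authors' conserved table, 11 of 57 sequences with enough reads were higher and 12 were lower in the after library. miR171d (TGAGCCGGACCAATATCACT) had 22 reads before and 1857 after, a log2 ratio of 6.50, and miR3627a (TGTCGCTGGAGAGATGGCACTT) had 510 and 3847 (3.02). They were followed by miR479 (2.64), miR399a (2.61) and the entry named miR398 (1.82). The sequence of miR399a is listed as a star strand, the partner of the guide strand, while the miR399 family counted from guides had -0.95. Its reads are counted again with the star strands below. The lowest were miR477b (-2.20), miR171f (-2.17), miR156a (-2.02), miR159 (-1.78) and miR397b (-1.71). miR156a was the most abundant entry in both libraries, with 59201 and 13651 reads, and miR164a (-0.95) and miR167a (-0.83) followed before topping. The form of miR171d that is 1 nt longer, with 318 and 391 reads, had a log2 ratio of 0.40, and the form that is 1 nt shorter, with 21 and 148 reads, had 2.92. Scaled by the sum of the table, 25 sequences were higher and 2 were lower.

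Among the new miRNAs of the authors' table, 11 of 67 sequences with enough reads were higher and 8 were lower. The most abundant were miRn38a with 2471 reads before and 2486 after, miRn23a with 2174 and 1395, miRn70 with 1223 and 220, and miRn61 with 1171 and 2035. The highest ratios rested on few reads before topping, as for miRn28 with 2 and 32 reads (ratio 17.2, 4.38 to 148), miRn57a with 3 and 47 (16.8, 5.41 to 84.4) and miRn66 with 2 and 23 (12.3, 3.05 to 108). miRn13b (log2 ratio 2.49) and miRn1a (2.20) followed. The lowest were miRn70 (-2.37), miRn11b (-2.07), miRn19 (-1.90), miRn12 (-1.71) and miRn74 (-1.31). The sequences of miRn11b, miRn27a, miRn15 and miRn48 are the most abundant tags of miR6024, miR6025, miR6019 and miR6020. Their reads were therefore also counted in those families above and are not a separate result. Scaled by the sum of the conserved table, 24 sequences were higher and 2 were lower. Of 124 sequences compared with the fold changes in the authors' deposited table, 123 had the same sign, and miRn49 was given there a fold of 2 while its tag had 212 reads before and 102 after topping.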

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

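All tests in this part were chosen after the results they bear on had been seen. Virus-like reads, which belong to no planned comparison, lay far above the limit of a zero count, with 213624 reads translating to the TMV coat protein after topping and 40445 translating to the PVY coat protein before topping. Chance matching is argued against, since the smaller of both excesses over the CMV background was 430-fold. Virus RNA broken without Dicer cutting is argued against, since 58.7% of reads on the TMV coat gene were 21 or 22 nt long, against 26.9% of ribosomal fragments in the same library. Infection of the sampled roots apart from topping and an effect of topping cannot be told apart, because there was 1 library per condition.

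Star strands, the partners of the guide strands in the miRNA duplex, were not compared with their guides above, although some entries of the authors' tables, such as miR399a and miRn23a, have a listed star sequence. miR165/miR166 star had 9085 reads after topping and 1620 before. In 15 of 17 families the star log2 ratio exceeded that of the guide, with a median difference of 0.93, and miR170/miR171 and miR398 went the other way. In the 11 families whose star reads had not been seen before listing, 10 showed this direction. Of these 10, miR168, miR390, miR403 and miR827 had a counting interval of the difference that included 0. For miR160, miR396, miR398, miR399, miR408 and miR482/miR2118 the listed star had more reads than the guide in both libraries. The strand names may therefore not hold for those families. Scaling is argued against as the whole cause, since it moves both strands alike and would leave a difference near 0. Guides with other 3′ ends are argued against as the whole cause, since counting every end gave a median of 1.06. Infection or topping cannot be told apart as a cause with 1 library per condition.

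Reads under 18 nt numbered 1679369 after topping and 637305 before, and the clean reads were also shorter. Reads on the library-specific contigs are argued against as the cause of the shorter clean reads, since the difference at 18 to 20 nt was 6.67 percentage points without them. Reads under 18 nt were not compared with the contigs, so this does not bear on their excess. A size window set lower on the gel may account for the shift: ribosomal fragments, which Dicer does not cut, had a ratio of 1.81 at 18 nt and of 0.137 at 28 nt. The listed tRNA ends other than alanine tRNA had ratios of 1.23 at 18 nt and 0.142 at 28 nt, but 0.350 at 20 nt, and alanine tRNA, which held 567299 of the 583215 listed tRNA reads after topping, had 2.15 at 22 nt and 2.29 at 24 nt. More broken RNA after topping stays open, since all ribosomal fragments had a ratio of 1.05, which breakage to below 18 nt would also allow, and it cannot be told apart from the gel window here.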

How the results depend on the processing

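No paired analysis was possible because each condition had 1 library. Scaling or profiles without reads on the library-specific contigs were chosen after seeing the data, and the cause of a change was not tested unless given. Against 2 families higher and 7 lower, scaling by the family sum gave 9 and 0, TMM 7 and 1, and DESeq2 size factors 6 and 1, since each moves every log2 ratio up by one amount. Exact matching gave 0 families higher, a minimum of 100 reads gave 1, and a ratio of 1.5 gave 4 higher and 15 lower. miR398 (2.07) changed sign under exact matching (-1.71) and without mismatches (-2.07), both of which drop its most abundant variant, and miR4376 (-1.07) changed sign under the family sum (0.020). In the conserved table (11 higher, 12 lower), scaling by its sum gave 25 and 2, and a ratio of 1.5 gave 20 lower. Leaving reads on the library-specific contigs out of the total gave 11 and 8 there. In the new table (11 higher, 8 lower), scaling by the conserved sum gave 24 and 2, a ratio of 1.5 gave 17 and 16, and leaving out the contig reads gave 14 and 7. Scaled by the family sum, list medians were 0.54 (auxin), 0.20 (development), 0.37 (nutrient), 2.06 (copper), 0.27 (defence), 0.89 (silencing machinery) and 0.020 (Solanaceae). The log2 ratio of summed reads was -0.65 for auxin, -1.15 for development, 1.63 for copper, -0.53 for defence and -0.11 for silencing machinery. Without these reads in the total, medians were -0.41 for auxin, -0.74 for development, -0.061 for silencing machinery and -0.93 for Solanaceae. The difference at 18 to 20 nt (6.77 points) was 6.71 over distinct tags, 8.43 without the 100 most abundant tags, 5.77 within 18 to 26 nt and 6.67 without reads on the library-specific contigs. At 24 nt (-2.75 points) these settings gave -3.59, -3.43, -3.63 and -2.04. Uracil at 21 nt (-5.85 points) differed by -1.04 over distinct tags and -4.59 without those reads, and adenine at 24 nt (-5.79 points) by -2.78 and -5.66. Thinned distinct tags had a ratio of 0.896, and 0.837 for tags with at least 2 reads. Of 201 alternative values of the 26 named families, 37 changed sign, 14 of them under the family sum, and 3 of the 37 belong to called families. Among families not called in the main setting, exact matching turned miR403 from 0.71 to -1.35, miR169 from -0.48 to 1.10 and miR6020 from 0.03 to -0.27. Matching without mismatches turned miR399 from -0.95 to 1.10 and miR6020 to -0.28. Depth limits families with few reads, such as miR2111 with 7 and 21 reads.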

Other observations

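The values in this part were chosen after the data had been seen. The sequence listed as miRn38a has 19 nt, while the most abundant tag of the before library extends it by 2 nt and had 201752 reads before and 157098 after topping, against 2471 and 2486 for the listed form. Of the 30 families with enough reads, 16 had their most abundant tag in the authors' tables, and the main forms of miR156/miR157 and miR165/miR166 were not among them.

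Among 17 families, 14 had a larger share of guide reads 1 nt short of the listed end in the after library, 8 of them with intervals apart, and the median was 1.51% before and 4.35% after topping. Ribosomal fragments were also shorter in that library, with a ratio of 1.81 at 18 nt and 0.137 at 28 nt. Near the guide lengths their ratios differed less, at 1.15 for 20 nt, 1.04 for 21 nt and 1.12 for 22 nt. Fragments of alanine tRNA, which held most of the listed tRNA reads, had ratios of 0.999 at 20 nt and 2.29 at 24 nt. The other listed tRNA ends had 0.350 and 0.935. For miR168 the share was 1.51% (1.22 to 1.87) before and 9.71% (8.87 to 10.6) after, and for miR403 it was 39.8% and 70.4%. All 3 forms of miR3627a were higher in the after library, with log2 ratios of 3.02, 2.12 and 2.60. Among tRNA ends, glycine GCC fragments had a ratio of 0.318 (0.304 to 0.333), opposite to alanine fragments at 1.75.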
